A study of Mus musculus with 24 samples.

How the data were processed

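The series holds a table of raw counts per gene name, deposited by the authors, for 24 libraries. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20, trimmed with cutadapt 1.18, aligned to mm10 with STAR 2.7.0f and counted per gene with featureCounts, with Subread 2.0.3 named and no separate version given for featureCounts. The notes do not state the annotation release, the strand setting or how reads with several alignments were counted. All 55341 gene names are in GENCODE vM21, 55297 of them with the same coordinates, so that annotation supplied length and GC content. The count values are whole numbers as deposited. No value column outside the 24 libraries was used.

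Samples were grouped into 12 groups of 2 per the labels, by IPTG, construct and treatment. Replicate 2 of C1-C2 in ethanol has a title and a treatment label that disagree, and it was grouped by its title. The groups, the comparisons, the gene lists and the main alternatives were chosen before the data were examined.

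Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (robust, TMM factors) in R 4.3.3, in a model with a mean for each of the 12 groups, which leaves 12 residual degrees of freedom. The low-count filter of edgeR kept 16934 genes and removed 38407. The median biological coefficient of variation was 6.43%. There were 20 comparisons, 16 of pairs of groups and 4 of dexamethasone responses, in the plan. P-values were adjusted with the method of Benjamini and Hochberg over all tested genes of a comparison, and a gene was called at an adjusted p under 0.05. DESeq2 1.42.0 was the other tool.

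The 20 fixed gene lists, with 455 genes, were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 20 lists of a comparison. The 16 recovery tests used fry of limma on signed genes that had been called in the other treatment. Ratios of genes with few counts carry 95% exact binomial intervals, and groups with few reads were set to a floor of 3 counts.

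Genes were named by a fixed rule: up to 8 higher and 8 lower genes of largest fold change in the knockdown, dexamethasone and wild-type NIPBL comparisons, 5 and 5 in the mutant comparisons, and up to 8 of smallest adjusted p in the differences of responses. They needed an adjusted p under 0.05, a mean of at least 1 CPM and both libraries of 1 group beyond both of the other, and gene models without a name were passed over. Up to 4 members of each list, Nipbl and Mau2 were added. The report prefers those whose call held with any 1 library left out.

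The method was tested on simulated data with 16563 genes. Counts were drawn independently for each gene and library, with 1 spread per gene for all groups. A library that stands apart, or structure shared between genes, was not simulated. The rates below may therefore not carry over to these libraries. In the knockdown comparison in ethanol, 65% of simulated 1.5-fold and 91.9% of simulated 2-fold changes were called, and 2.81% of the calls were false. In dexamethasone 96.0% of simulated 2-fold changes were called and 6.63% of the calls were false. With no simulated difference 0 genes were called with edgeR. A simulated GC trend with no other change gave 3295 calls, and 0 after removal of the trend. For differences of responses 10% of simulated 1.22-fold, 56.8% of 1.41-fold and 80.3% of 1.73-fold changes were called, so small differences would mostly be missed. The recovery measure gave -1.45% over 196 genes in ethanol, where no recovery was simulated. In dexamethasone it gave 50.8% over 178 genes, where a recovery by 0.5 of the distance was simulated.

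The ethanol libraries hold 32.5 to 42.7 M counts and the dexamethasone libraries 45.0 to 72.9 M. Genes Gm26917 and Gm42418 took 12.0% to 13.3% of the counts in ethanol and 12.7% to 16.1% in dexamethasone. The correlation of log2 CPM between the 2 replicates of a group was 0.997 to 0.999, and chi-square per degree of freedom ran from 5.92 to 22.9, with the highest in wild-type NIPBL in dexamethasone. The first principal component held 44.1% of the variance and separated the treatments, and the second held 10.7%. Replicate 1 of wild-type NIPBL in dexamethasone stood apart from its replicate 2 on the second and the next component.

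The alternatives tried were RLE factors, no filter, a strict filter, a replicate block, a replicate block within treatment, DESeq2, only the libraries compared, each library left out in turn, the library with disagreeing labels left out or moved, an estimated correlation for the lists, and other gene sets for recovery. Added after results were seen were fry tests of 2 lists for each construct against empty vector, fry tests of the response of the induced list between states with and without IPTG, a fit without the 2 most abundant genes, removal of a smooth trend with length and GC content, RLE factors for the lists and lists with each library left out. No library was left out of the main analysis.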

Results

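The libraries hold RNA of a mouse mammary adenocarcinoma cell line. The cells carried a short hairpin RNA against NIPBL that IPTG switches on, together with a piggyBac construct that was empty or encoded NIPBL. NIPBL is the protein that, with MAU2, loads the cohesin ring onto chromatin and drives the extrusion of chromatin loops. The constructs were an empty vector, wild-type NIPBL and mutants that the labels call C1, C2 and C1-C2 without saying what they change. The 24 libraries form 12 groups of 2. The empty-vector cells were measured without and with IPTG and the other constructs with IPTG, each after ethanol or after 100 nM dexamethasone for 2 hours. No group had IPTG without the hairpin. The knockdown comparisons alone therefore cannot tell loss of NIPBL from an effect of IPTG or the hairpin. Dexamethasone is a synthetic ligand of the glucocorticoid receptor. The labels do not say that the 2 replicates of a group are separate cultures, so the p-values measure only the spread between these samples. Levels are counts scaled to library size (CPM), given as mean ± SD with n = 2.

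Nipbl (mm10, chromosome 15, 8290617 to 8444463) lay between 151 and 186 CPM in the 4 libraries without IPTG and between 48.0 and 73.3 CPM in the 20 libraries with IPTG. In empty-vector cells in ethanol it fell 2.84-fold with IPTG, from 181 ± 6.57 to 63.8 ± 1.75 CPM (SD, n = 2; edgeR adjusted p = 1.39e-08). In dexamethasone it fell 2.75-fold, from 153 ± 2.07 to 55.5 ± 1.48 CPM (SD, n = 2; edgeR adjusted p = 1.01e-08). No rise of the counts assigned to Nipbl passed the test in cells with wild-type NIPBL, and the mutants were not tested against empty vector for this gene. Wild-type NIPBL cells differed from empty-vector cells with IPTG by 0.06 on the log2 scale in ethanol (edgeR adjusted p = 0.894) and by 0.13 in dexamethasone (edgeR adjusted p = 0.509). The sign of both small differences turned when 1 library was left out, to -0.03 without replicate 1 of wild-type NIPBL in ethanol and to -0.01 without its replicate 1 in dexamethasone. The files do not tell whether transcripts of the constructs were counted as Nipbl. Mau2, the partner of NIPBL, lay between 54.4 and 71.8 CPM in the libraries with IPTG and did not pass the test after knockdown in ethanol (58.7 ± 1.85 against 61.4 ± 1.37 CPM, SD, n = 2; edgeR adjusted p = 0.527).

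**Figure D1:**
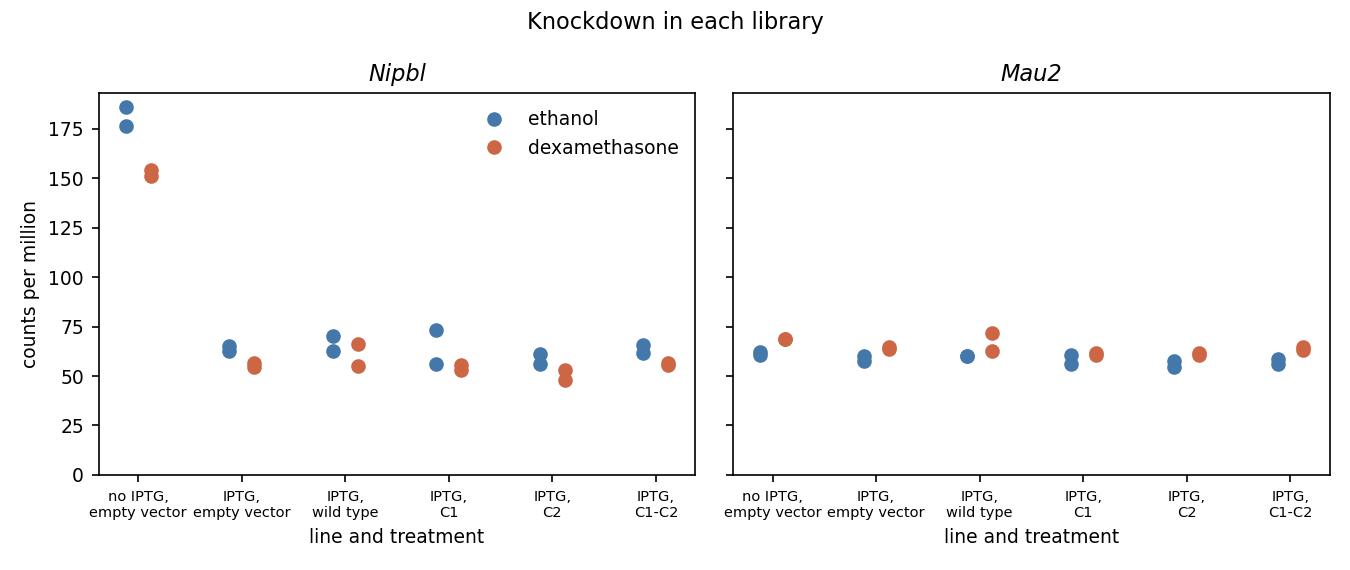
Nipbl and Mau2 in CPM, on an axis that starts at 0, with a point for each of the 24 libraries by construct, IPTG and treatment. For Nipbl the 4 libraries without IPTG lie at 151 CPM or more, and the 20 libraries with IPTG at 73.3 CPM or less.

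After knockdown in ethanol, the genes with the largest falls were clustered protocadherins, cell surface adhesion molecules best known from neurons. Pcdhgb7 (chromosome 18, 37751600 to 37841873) fell 9.96-fold, from 4.12 ± 0.0418 to 0.406 ± 0.107 CPM (SD, n = 2; edgeR adjusted p = 2.55e-08). Pcdhb22 fell 8.97-fold (edgeR adjusted p = 0.000148). Among the other genes that fell were Thbs2, a matrix glycoprotein (3.90-fold), Scara5, a scavenger receptor that takes up ferritin (3.62-fold), the chemokine gene Ccl7 (3.22-fold) and Rapgef3, which encodes the cAMP sensor EPAC1 (2.75-fold, from 30.4 ± 2.15 to 11 ± 0.705 CPM, SD, n = 2). Cd28, a T cell co-stimulatory receptor, rose 6.54-fold, from 0.371 ± 0.0701 to 2.45 ± 0.794 CPM (SD, n = 2; edgeR adjusted p = 2.81e-06). Dynap rose 5.71-fold, the teneurin gene Tenm4 4.80-fold and Psca, a cell surface antigen, 4.65-fold. In all, 2270 of 16934 tested genes passed at an adjusted p under 0.05 with edgeR, 1213 higher and 1057 lower, of which 162 and 96 changed at least 2-fold.

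Of the 28 measured clustered protocadherins, 15 fell, 0 rose and 13 did not pass, while 21 fell when adjusted over the list alone. Their median log2 change was -2.43, or -2.16 with the 9 members at or under the floor of 3 counts per group set to that floor, and the camera call held with an estimated correlation (adjusted p = 0.0262). Pcdhgb6 had 3 counts against 74, a ratio of 23.3 (95% exact binomial interval 7.67 to 116; such intervals cover counting error only). The γ protocadherin genes overlap on the same strand and Pcdhb22 overlaps Pcdhb21, so counts of single members are uncertain. Glucocorticoid-repressed inflammatory genes fell as a group, with 5 of 12 lower, 1 higher and 8 lower when adjusted over the list alone. The call held with an estimated correlation (adjusted p = 0.0262). Ccl2, a monocyte chemoattractant, fell 2.24-fold, from 21.01 ± 2.64 to 9.38 ± 0.121 CPM (SD, n = 2; edgeR adjusted p = 1.18e-06).

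Interferon-stimulated genes, which act in antiviral defence, moved the other way in ethanol. Of 21 measured, 14 rose and 0 fell, and adjusted over the list alone 20 rose and 1 fell. The median log2 change was 0.56, or 0.55 with 1 member at its floor, and the call was lost with an estimated correlation (adjusted p = 0.148). An effect of IPTG or the hairpin on this list, apart from loss of NIPBL, was not tested. Oasl2 rose 2.07-fold, Rsad2, which encodes viperin, 1.74-fold and Stat2 1.26-fold, and Mx2 had 37 counts against 3, a ratio of 13.1 (95% exact binomial interval 4.13 to 66.2). Among 19 p53 targets, 6 fell and 1 rose (8 and 2 adjusted over the list alone; adjusted p = 0.161 with an estimated correlation). The kinase gene Plk2 fell 2.22-fold (edgeR adjusted p = 9.32e-11), the stress cytokine gene Gdf15 2.74-fold and Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, 1.53-fold. Of 24 cell cycle and replication genes, 12 fell and 0 rose (13 adjusted over the list alone; adjusted p = 0.205 with an estimated correlation), among them Mcm3 of the replicative helicase (1.70-fold) and cyclin E2, Ccne2 (1.99-fold). Of 21 matrix and mesenchymal genes, 7 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 0.0989 with an estimated correlation), with the collagen genes Col6a2 2.44-fold, Col6a1 1.94-fold and Col5a1 1.53-fold lower. Of 27 Hox genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.152 with an estimated correlation). Hoxc6 was 1.58-fold and Hoxb9 1.29-fold higher, and Hoxc13 was 1.34-fold lower. Of 22 replication-dependent histone genes 7 fell and 0 rose (13 adjusted over the list alone; adjusted p = 0.161 with an estimated correlation).

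Among 15 cohesin genes in ethanol, 3 fell and 1 rose, and camera did not call the list (adjusted p = 0.1). Beside Nipbl, Pds5b fell 1.25-fold and Esco2 1.25-fold, whereas Stag1, a subunit of the cohesin ring, rose 1.49-fold, from 149 ± 6.06 to 222 ± 0.768 CPM (SD, n = 2; edgeR adjusted p = 2.42e-08). Slc7a11, the cystine transporter, rose 2.90-fold. Glucocorticoid-induced genes did not move together before hormone, with 4 of 29 higher, 4 lower and a median log2 change of 0.04. Ampd3 rose 1.68-fold and Angptl4 fell 2.2-fold among them. Nr3c1, the glucocorticoid receptor gene, did not pass (181 ± 1.51 against 198 ± 2.63 CPM, SD, n = 2; edgeR adjusted p = 0.0785). The number of genes past the threshold fell to 1136 without replicate 2 of IPTG empty vector in ethanol, 1164 without replicate 1 of no IPTG in ethanol and 1485 without replicate 1 of IPTG empty vector in ethanol.

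In dexamethasone the knockdown again lowered protocadherins and raised many of the genes that had risen in ethanol. Pcdhb22 fell 23.99-fold (edgeR adjusted p = 4.61e-06) and Pcdhgb7 16.5-fold, from 4.36 ± 0.191 to 0.262 ± 0.0853 CPM (SD, n = 2; edgeR adjusted p = 6.08e-10). Selenbp1 fell 4.11-fold, Scara5 3.88-fold, Thbs2 3.81-fold, Rapgef3 3.45-fold, Fam167a 3.18-fold and Gdf15 2.98-fold. Cdh17, an epithelial cadherin, rose 9.43-fold (edgeR adjusted p = 0.000307), S100a7a 6.96-fold, Cd28 5.91-fold, Dynap 5.70-fold and Tenm4 5.64-fold. In all 2854 genes passed, 1416 higher and 1438 lower, of which 221 and 138 changed at least 2-fold. Between both treatments, 801 genes were higher in both where chance overlap would give 101, 758 were lower in both where chance would give 89.8, and 4 called genes had opposite directions.

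Knockdown in dexamethasone lowered 16 and raised 3 of the 29 glucocorticoid-induced genes, and adjusted over the list alone the counts were the same. The median log2 change was -0.34 (adjusted p = 0.0581 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor and a standard marker of its activity, fell 1.75-fold, from 703 ± 6.96 to 402 ± 6.33 CPM (SD, n = 2; edgeR adjusted p = 1.29e-07). Cebpd, a transcription factor gene, fell 1.95-fold, whereas Suox, sulfite oxidase, rose 1.43-fold and Ampd3 1.34-fold. Among the 12 inflammatory genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.0581 with an estimated correlation). Lif fell 1.69-fold, while the chemokine gene Cxcl5 rose 2.87-fold, from 5.58 ± 1.45 to 15.8 ± 2.22 CPM (SD, n = 2; edgeR adjusted p = 0.000898). Of the protocadherins 18 of 28 fell and 0 rose (22 adjusted over the list alone; median log2 change -2.19, or -2.08 with 7 members at their floor; adjusted p = 0.02 with an estimated correlation).

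The remaining lists in dexamethasone were these. Of the interferon-stimulated genes 15 of 21 rose (17 adjusted over the list alone; adjusted p = 0.0598 with an estimated correlation), with Rsad2 2.53-fold, Oasl2 2.26-fold and Ifit1 1.47-fold higher. Of the p53 targets 9 of 19 fell and 1 rose (10 and 1 adjusted over the list alone), and this call held with an estimated correlation (adjusted p = 0.0412). Eda2r, a receptor of the tumour necrosis factor family, was 2.42-fold, Plk2 2.38-fold and the antiproliferative gene Btg2 2.21-fold lower. Of the histone genes 17 of 22 fell (19 adjusted over the list alone; adjusted p = 0.0581 with an estimated correlation), such as Hist1h2bj, 1.28-fold. Of the cell cycle genes 9 of 24 fell (11 adjusted over the list alone; adjusted p = 0.259 with an estimated correlation), and of the matrix genes 7 of 21 fell and 1 rose (9 and 2 adjusted over the list alone; adjusted p = 0.0581 with an estimated correlation). Immediate early genes, 7 of 18 lower and 3 higher, were not called as a list (camera adjusted p = 0.0563), but Myc was 1.62-fold, Klf4 1.70-fold and Ier2 1.55-fold lower. The count of 2854 fell to 1374 without replicate 2 of IPTG empty vector in dexamethasone and to 1855 without replicate 1 of no IPTG in dexamethasone.

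Dexamethasone for 2 hours raised the known targets of the glucocorticoid receptor and lowered inflammatory genes in cells without IPTG. Per1, a clock gene with a receptor binding site in its promoter (chromosome 11, 69095217 to 69109960), rose 13.4-fold, from 22.4 ± 0.35 to 299.5 ± 11.7 CPM (SD, n = 2; edgeR adjusted p = 1.99e-25). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper (chromosome X, 140539528 to 140600659), rose 22.9-fold, from 12.8 ± 1.81 to 292 ± 8.57 CPM (SD, n = 2; edgeR adjusted p = 8.49e-20). The siderophore-binding protein gene Lcn2 rose 77.6-fold, Slc25a48 41.6-fold, Prr15l 32.6-fold, the acute phase gene Orm3 24.5-fold, the kinase gene Sgk1 8.57-fold and Ampd3 5.21-fold. Fam107a had 568 counts against 1, a ratio of 437 (95% exact binomial interval 78.2 to 17300), and Greb1 144 against 1, a ratio of 111 (interval 19.6 to 4410). Vmn1r43 rose 73.4-fold, but it overlaps Vmn1r42 on the same strand and its count is uncertain. The chemokine genes Cxcl5 and Ccl2 fell 9.001-fold and 6.80-fold, Usp17la 6.99-fold, the urokinase gene Plau 5.91-fold, Rasl11a 5.003-fold, Pparg, a nuclear receptor of fat cell differentiation, 4.99-fold, Cxcl1 3.61-fold and the cyclooxygenase gene Ptgs2 3.53-fold. The mitochondrial transfer RNA gene mt-Tl1 was 30.7-fold lower and Phpt1, which overlaps Mamdc4, 5.06-fold lower. For mt-Tl1 a library batch and the hormone cannot be told apart, as the library names run in a separate block for each treatment. Of the 15 measured genes on the list of mitochondrially encoded genes, 1 rose and 0 fell with a trend on transcript length and GC content removed (median log2 change 0.07). Nr3c1, the receptor's own gene, fell 1.89-fold, from 198 ± 2.63 to 105 ± 0.176 CPM (SD, n = 2; edgeR adjusted p = 7.43e-14).

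Of the 29 glucocorticoid-induced genes, 26 rose without IPTG, 0 fell and 3 did not pass (27 rose adjusted over the list alone). The median log2 change was 2.38 and the call held with an estimated correlation (adjusted p = 0.00116). Of the 12 inflammatory genes 9 fell and 1 rose, also adjusted over the list alone, with a median of -1.35 (adjusted p = 0.00182 with an estimated correlation). Across all 6 cell states, 1613 genes were higher and 1562 lower in every state, 300 and 100 of them at least 2-fold. The medians of the induced list were 2.38 without IPTG, 2.04 in IPTG empty vector, 1.98 in wild-type NIPBL, 1.77 in C1, 2.03 in C2 and 1.87 in C1-C2. Its call held with an estimated correlation in each of the 5 states with IPTG as well (adjusted p = 0.000332 to 0.000562). The clock repressor gene Nfil3 rose 6.56-fold without IPTG. Cdkn1a rose 2.29-fold while Plk2 fell 3.05-fold and the stress gene Ier3 3.52-fold. Of 15 circadian clock genes 7 rose and 4 fell, and camera did not call the list (adjusted p = 0.157). Of the 15 cohesin genes 12 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.0506 with an estimated correlation), and with a trend on transcript length and GC content removed 3 fell. Of 30 ribosomal protein genes, which also report on coverage and RNA quality, 20 rose and 2 fell (adjusted p = 0.336 with an estimated correlation).

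A trend of GC content split the libraries by treatment, and the number of dexamethasone calls fell when it was removed together with that of length. Without IPTG 6438 genes passed with edgeR, 3359 higher and 3079 lower, of which 578 and 364 changed at least 2-fold. In the states with IPTG, 5510 passed in empty vector, 4823 in wild-type NIPBL, 5447 in C1, 5500 in C2 and 5464 in C1-C2. The trend was measured over the 12369 tested genes with a positive mean log2 CPM. The genes of highest minus those of lowest GC content (the outer of 4 equal groups) ran from -0.26 to -0.16 log2 units in the 12 ethanol libraries. In the 12 dexamethasone libraries the difference ran from 0.10 to 0.28. With this trend and that of length removed, 3858 genes passed without IPTG and 46.8% of the 6438 calls were kept, among them 772 of the 942 calls of at least 2-fold. The library names also run in a separate block of numbers for each treatment, so the batch and the treatment cannot be told apart by a fit.

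**Figure D2:**
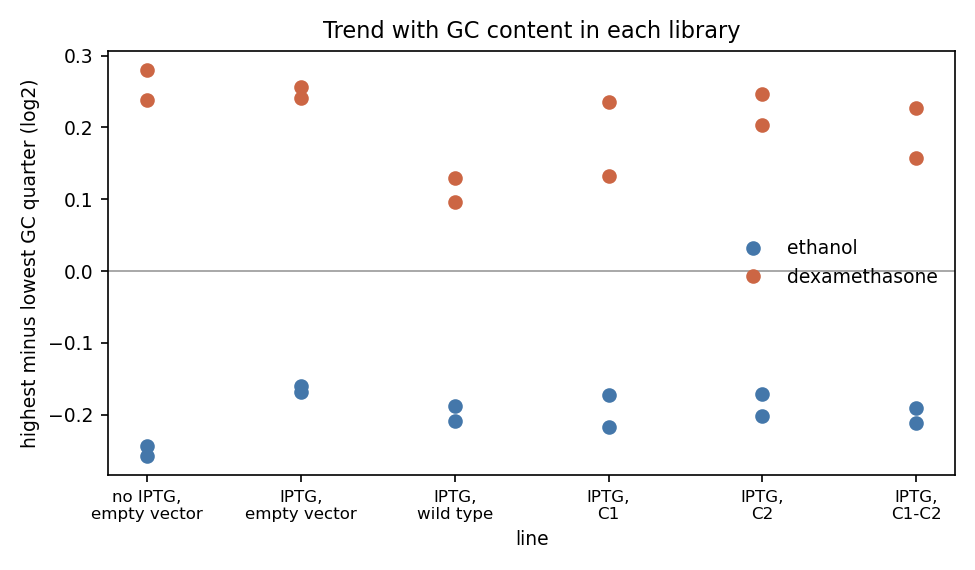
Median log2 level of the genes of highest GC content minus that of the genes of lowest (the outer of 4 equal groups), each gene relative to the other libraries, with a point for each of the 24 libraries by construct and treatment. All 12 ethanol libraries lie between -0.26 and -0.16, and all 12 dexamethasone libraries between 0.10 and 0.28.

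With IPTG, cells with wild-type NIPBL had higher protocadherins than empty-vector cells. As a set, the genes of the knockdown lay nearer to their level without IPTG. The labels name 1 line per construct. Here and below, a difference between these lines was not tested and cannot be told apart from an effect of wild-type NIPBL. Pcdhb22 was 16.1-fold higher than in empty-vector cells in ethanol (edgeR adjusted p = 3.52e-05) and 37.6-fold in dexamethasone (edgeR adjusted p = 4.78e-06). Pcdhgb7 was 6.48-fold and 9.07-fold higher, and Pcdhb14, which overlaps no other gene, 3.33-fold in ethanol (8.55 ± 0.608 against 2.57 ± 0.347 CPM, SD, n = 2; edgeR adjusted p = 1.17e-07) and 3.19-fold in dexamethasone (edgeR adjusted p = 1.06e-07). Tpsab1, a mast cell tryptase gene, was 7.57-fold and 8.06-fold higher, Dtna, encoding dystrobrevin alpha, 2.98-fold and 2.76-fold, and Cd48 3.17-fold in ethanol. Cpne7 was 3.70-fold lower in ethanol, and Slc52a3, a riboflavin transporter gene, 2.06-fold in ethanol and 2.00-fold in dexamethasone. Stag1 was lower in both treatments, 1.37-fold in ethanol (edgeR adjusted p = 7.78e-06) and 1.31-fold in dexamethasone. Fkbp5 was 1.37-fold higher in dexamethasone (549 ± 28.8 against 402 ± 6.33 CPM, SD, n = 2; edgeR adjusted p = 0.00135), and Nrip1, a corepressor of nuclear receptors, 1.36-fold (edgeR adjusted p = 8.11e-06). Lncenc1 rose 3.26-fold and Plk2 1.41-fold in dexamethasone, and Dmtn fell 1.90-fold.

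Protocadherins were the list that differed most often between wild-type NIPBL and empty-vector cells. In ethanol 14 of 28 rose and 0 fell (24 adjusted over the list alone), with a median of 2.18, or 1.94 with members at their floor, and in dexamethasone 19 rose and 0 fell (25 adjusted over the list alone), with a median of 2.82, or 2.59. The call held with an estimated correlation in both (adjusted p = 0.001 and 0.000892). Glucocorticoid-repressed inflammatory genes were higher in ethanol, with 2 of 12 called (3 adjusted over the list alone; adjusted p = 0.0161 with an estimated correlation). In dexamethasone 4 of 12 were higher (5 adjusted over the list alone), and the call was lost with an estimated correlation (adjusted p = 0.166). Interferon-stimulated genes were lower in ethanol, with 2 of 21 called, both also adjusted over the list alone (median -0.25; adjusted p = 0.338 with an estimated correlation). In all 196 genes passed in ethanol, 107 higher and 89 lower, and 712 in dexamethasone, 400 higher and 312 lower. Of the genes called after knockdown in ethanol and with wild-type NIPBL in dexamethasone, 201 and 165 had opposite directions, where chance would give 22.35 and 24.97, and 3 and 3 had the same direction. The ethanol count was 83 and 66 without replicates 1 and 2 of IPTG empty vector and 73 and 93 without replicates 1 and 2 of wild-type NIPBL. The dexamethasone count was 241 and 165 without replicates 1 and 2 of empty vector, 193 without replicate 1 of wild-type NIPBL and 1441 without its replicate 2. Replicate 1 stood apart from replicate 2 in dexamethasone, at 23.67 against 5.56 on the second principal component, near the libraries without IPTG (24.85 to 34.05), and at -31.48 against -0.86 on the third.

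The share of the knockdown change that each construct made good was measured on genes called in the other treatment, so that genes were not chosen on the libraries in which they were scored, and Nipbl itself was left out. The remaining 2853 genes called in dexamethasone moved in ethanol by a median of 0.27 log2 units between no IPTG and IPTG empty vector. Wild-type NIPBL moved them by 0.0981 in the same direction, 36.3% of that distance, and 81.7% of the genes lay on the side of no IPTG (fry adjusted p = 4.33e-05). The C2 mutant reached 19.3% (fry adjusted p = 0.00624), and C1 and C1-C2, at 12% and 10.4%, did not pass (fry adjusted p = 0.0596 and 0.0884). Both lie near the threshold. For the ethanol test of C1 the genes and the spread come from libraries of both treatments, and it passed without replicate 1 of no IPTG (0.0402), replicate 2 of IPTG empty vector (0.01) or replicates 1 or 2 of wild-type NIPBL (0.0421 and 0.0388), all in dexamethasone, and with the length and GC trend removed (0.0382). C1-C2 passed without replicate 1 of no IPTG (0.0489) or replicate 2 of IPTG empty vector (0.0184) in dexamethasone. In dexamethasone, over the 2269 genes called in ethanol, wild-type NIPBL reached 48.0% (fry adjusted p = 9.26e-08), C1 16.1% (0.00197), C2 21.5% (0.000285) and C1-C2 15.3% (0.00224). Over the fewer genes changed at least 1.5-fold the mutant calls ended although the median shifts were larger. In dexamethasone the shift was 0.0726 against 0.0479 for C1 (fry adjusted p = 0.0643), 0.0922 against 0.0642 for C2 (0.0681) and 0.0692 against 0.0455 for C1-C2 (0.117), and in ethanol 0.0588 against 0.0522 for C2 (0.173). Cells with each mutant fell short of cells with wild-type NIPBL in both treatments. The median differences were -0.0592, -0.0469 and -0.0693 for C1, C2 and C1-C2 in ethanol (fry adjusted p = 0.000926, 0.00675 and 0.000529) and -0.0912, -0.0815 and -0.0905 in dexamethasone (fry adjusted p = 1e-05, 3.38e-05 and 1.05e-05). The call for C2 in ethanol ended without replicate 1 of wild-type NIPBL in ethanol (-0.0345; fry adjusted p = 0.0547). Without replicate 2 of IPTG empty vector in dexamethasone the ethanol differences were larger, -0.0964, -0.0839 and -0.1072, and the dexamethasone shift of C1 from empty vector was 0.0303 in place of 0.0479. Fry tests the direction of a set as a whole and does not compare it with other genes. In each treatment no IPTG and all constructs were scored against the same IPTG empty-vector libraries, so their shifts are not independent of each other. A deviation that these empty-vector libraries share across treatments would move all constructs towards no IPTG. Choosing genes in the other treatment does not remove it. The labels name 1 line per construct, and the level of each construct is not known. A difference between lines or in level was not tested and cannot be told apart from an effect of a mutation or of wild-type NIPBL. In each treatment all mutants were compared with the same wild-type libraries, so their results are not independent of each other. In dexamethasone these include replicate 1, which stood apart from replicate 2. The same limits hold for the mutant comparisons below.

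**Figure D3:**
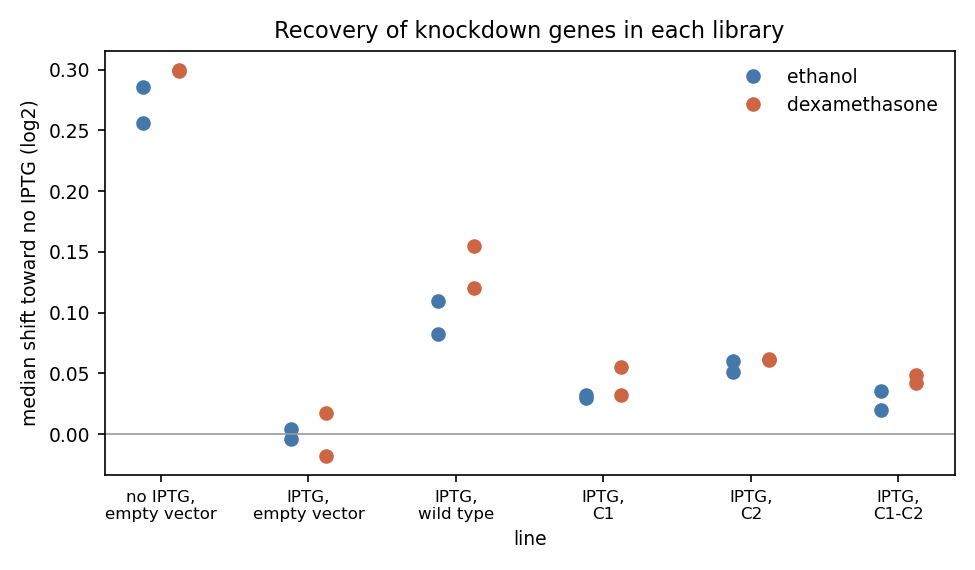
Median signed log2 difference from IPTG empty vector over the genes of the knockdown, with positive values towards no IPTG and a point for each library, by construct in ethanol (2853 genes) and dexamethasone (2269 genes). Wild-type NIPBL stands at 36.3% and 48.0% of the no-IPTG distance, and the mutants between 10.4% and 21.5%.

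The C1 mutant, compared with wild-type NIPBL, had lower Csn3, a milk casein gene, in both treatments. It was 4.74-fold lower in ethanol (0.548 ± 0.177 against 2.61 ± 0.06 CPM, SD, n = 2; edgeR adjusted p = 8.27e-06) and 4.28-fold in dexamethasone (edgeR adjusted p = 2.26e-06). The noncoding RNA gene Lncenc1 was 3.62-fold and 3.19-fold lower, Scara5 4.98-fold lower in dexamethasone, and Pcdhb14 2.01-fold lower in ethanol and 1.87-fold in dexamethasone. Fcho1, an endocytosis gene, was 4.06-fold and 3.13-fold higher, and Havcr2, which encodes the receptor TIM-3, 2.97-fold higher in dexamethasone. Stag1 was 1.33-fold and 1.30-fold higher and Btg2 1.89-fold and 1.86-fold lower. In dexamethasone Fkbp5 was 1.44-fold lower (380 ± 14.9 against 549 ± 28.8 CPM, SD, n = 2; edgeR adjusted p = 0.000254) and Nrip1 1.29-fold lower, and 8 of 29 glucocorticoid-induced genes were lower and 1 higher (13 and 2 adjusted over the list alone; adjusted p = 0.325 with an estimated correlation). Protocadherins were lower in 7 of 28 members in ethanol (17 adjusted over the list alone; median -1.34, or -1.19 with members at their floor), where the call held with an estimated correlation (adjusted p = 0.0208), and in 11 of 28 in dexamethasone (23 adjusted over the list alone; median -1.15, or -1.18; adjusted p = 0.0556 with an estimated correlation). In all 338 genes passed in ethanol and 902 in dexamethasone. The first count was 196 and 77 without replicates 1 and 2 of wild-type NIPBL and 77 without replicate 2 of C1 in ethanol, and the second 298 without replicate 1 of wild-type NIPBL and 300 and 216 without replicates 1 and 2 of C1 in dexamethasone.

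The C2 mutant, compared with wild-type NIPBL, had higher Ank2, which encodes the membrane adaptor ankyrin B, and lower protocadherins. Ank2 was 2.30-fold higher in ethanol (43.1 ± 3.91 against 18.8 ± 1.55 CPM, SD, n = 2; edgeR adjusted p = 1.81e-08) and 2.18-fold in dexamethasone (edgeR adjusted p = 3.22e-08). Cpne7 was 4.65-fold and 2.46-fold higher and Enpp5 3.38-fold higher in dexamethasone. Pcdhb14 was 3.02-fold lower in ethanol (edgeR adjusted p = 3.02e-07) and 3.28-fold in dexamethasone (edgeR adjusted p = 3.22e-08), Scara5 5.76-fold and the maltase gene Mgam 2.93-fold lower in dexamethasone, and Col6a2 2.08-fold and 1.95-fold lower. Of the protocadherins 10 of 28 were lower in ethanol (21 adjusted over the list alone; median -1.80, or -1.54 with members at their floor) and 19 in dexamethasone (22 lower and 1 higher adjusted over the list alone; median -2.18, or -2.21). Both calls held with an estimated correlation (adjusted p = 0.00983 and 0.0196). The p53 targets were lower in ethanol, with 4 of 19 called (6 adjusted over the list alone), and this also held (adjusted p = 0.0328 with an estimated correlation). Glucocorticoid-repressed inflammatory genes were lower in ethanol as well, with 3 of 12 called (4 adjusted over the list alone; median -0.09; adjusted p = 0.0462 with an estimated correlation), a camera call that ended without replicate 1 of C2 (adjusted p = 0.0605). Of the histone genes 8 of 22 were higher in dexamethasone (14 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). In all 339 genes passed in ethanol and 875 in dexamethasone. The first count was 135 and 87 without replicates 1 and 2 of wild-type NIPBL and 62 without replicate 2 of C2 in ethanol, and the second 226 and 1515 without replicates 1 and 2 of wild-type NIPBL and 128 without replicate 2 of C2 in dexamethasone.

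The C1-C2 mutant was set apart from wild-type NIPBL by Ms4a4d, a membrane protein gene, which was 9.70-fold higher in ethanol (5.04 ± 0.377 against 0.518 ± 0.0664 CPM, SD, n = 2; edgeR adjusted p = 4.23e-08) and 6.52-fold in dexamethasone (edgeR adjusted p = 1.41e-07). Cpne7 was 4.29-fold higher in ethanol. Lncenc1 was 2.66-fold and 3.32-fold lower, Cd48 3.04-fold and 3.03-fold, Dtna 2.60-fold and 2.51-fold, and Pcdhb14 2.52-fold and 2.24-fold. Plk2 was 1.44-fold lower in dexamethasone. Of the protocadherins 4 of 28 were lower in ethanol and 3 in dexamethasone (7 and 12 adjusted over the list alone; medians -0.80 and -1.11, or -0.80 and -1.13 with members at their floor; adjusted p = 0.0697 and 0.0614 with an estimated correlation). In all 130 genes passed in ethanol and 238 in dexamethasone. The first count was 59 and 32 without replicates 1 and 2 of wild-type NIPBL and 48 and 38 without replicates 1 and 2 of C1-C2 in ethanol, and the second 122 and 148 without replicates 1 and 2 of wild-type NIPBL and 43 and 44 without replicates 1 and 2 of C1-C2 in dexamethasone. Replicate 2 of C1-C2 in ethanol has a title that says ethanol and a treatment label that says dexamethasone. It was grouped by its title, and its Per1 (24.4 CPM), Tsc22d3 (12.3 CPM) and Fkbp5 (81.2 CPM) lie within the ranges of the other 11 ethanol libraries (22.2 to 26.6, 9.95 to 14.1 and 68.5 to 87.7 CPM) and below those of the 12 dexamethasone libraries (269 to 308, 148 to 298 and 370 to 708 CPM).

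Against empty vector with IPTG, protocadherins were higher as a set with C1 in both treatments, with 1 and 3 of 28 members called (medians 0.89 and 1.32; fry adjusted p = 0.00862 and 0.000754), and with C1-C2, with 2 and 3 called (medians 1.51 and 1.71; fry adjusted p = 0.00101 and 0.000151). With C2 they were higher as a set in dexamethasone with 2 called (median 0.74; fry adjusted p = 0.0266), and did not pass in ethanol with 0 called (median 0.25; fry adjusted p = 0.0842). In the comparison of wild-type NIPBL with empty vector, 9 of 28 members in ethanol and 7 in dexamethasone lay at or under the floor of 3 counts. Medians with the floor were not computed for the mutants against empty vector, so their size is uncertain. All constructs share the same empty-vector libraries in each treatment. Interferon-stimulated genes were lower as a set with wild-type NIPBL, with 2 of 21 called in each treatment (medians -0.25 and -0.19; fry adjusted p = 0.0468 and 0.045), where camera lost the call (adjusted p = 0.338 and 0.709 with an estimated correlation). With C1 the set was lower though 0 of 21 members were called in either treatment (medians -0.49 and -0.32; fry adjusted p = 0.0071 and 0.0266). With C2 and C1-C2 their medians lay between -0.12 and -0.04 and did not pass (fry adjusted p = 0.54 to 0.706).

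**Figure D4:**
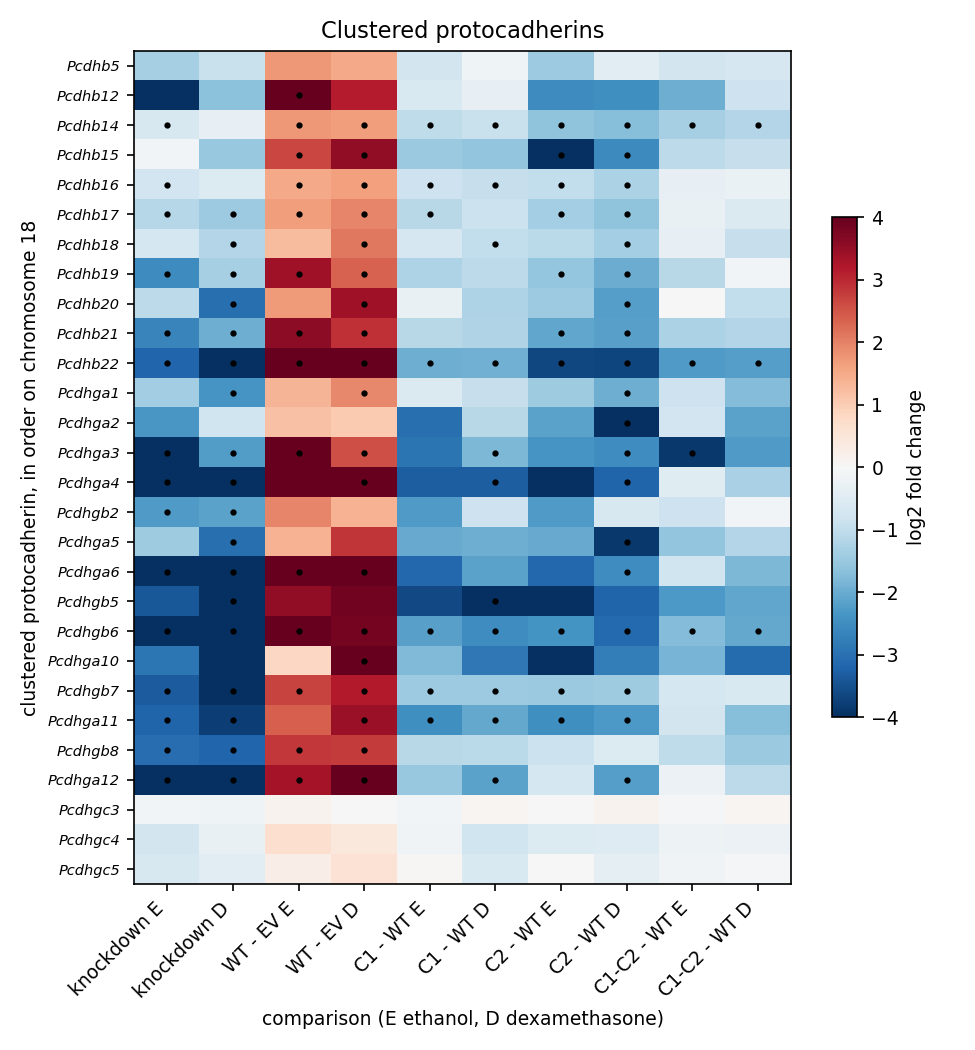
Log2 fold change (colour) of each of the 28 measured clustered protocadherins, in order on chromosome 18, in the knockdown, wild-type NIPBL and mutant comparisons in ethanol (E) and dexamethasone (D), with dots where the adjusted p is under 0.05. The medians are -2.43 and -2.19 for the knockdown, 2.18 and 2.82 for wild-type NIPBL against empty vector, and between -2.18 and -0.80 for the mutants against wild-type NIPBL.

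The last comparison asked whether cells responded differently to dexamethasone after knockdown, by testing the difference of both responses. The difference passed for 29 genes with edgeR, 26 with a lower and 3 with a higher signed log2 response after knockdown. In all 857 genes had an unadjusted edgeR p under 0.05, where chance would give 847. Of the 26, 24 were genes that dexamethasone raised without IPTG, as were 19.8% of all tested genes. The difference and that rise use the same libraries without IPTG, so the share of 24 in 26 is partly built in. A lower signed response is not always a smaller one, since a gene that fell with hormone can fall further. Tsc22d1 rose by 0.91 on the log2 scale without IPTG, and its change of 0.14 with IPTG did not pass (edgeR adjusted p = 0.0757). The difference was -0.77 (SE 0.084, edgeR adjusted p = 4.75e-05). Socs2, a feedback inhibitor of cytokine signalling, rose by 2.76 and 1.60 (difference -1.16, SE 0.142; adjusted p = 0.000268). The sphingosine kinase gene Sphk1 rose by 3.04 and 2.33, the small GTPase gene Rhob by 2.07 and 1.15, and Lfng, a glycosyltransferase that modifies Notch receptors, by 1.36 and 0.56. Notch1 changed by 0.33 and -0.45 and Snx18 by 0.31 and -0.13. Suox was the exception among the 8 genes of smallest adjusted p, with responses of 2.695 and 3.404. The count was 13 and 18 without replicates 1 and 2 of no IPTG in ethanol, 9 without replicate 2 of IPTG empty vector in ethanol, and 13 and 17 without replicates 1 and 2 of IPTG empty vector in dexamethasone.

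Over the 29 glucocorticoid-induced genes the response was smaller after knockdown, with a median difference of -0.33 on the log2 scale, and the call held with an estimated correlation (adjusted p = 0.0257). Over all genes 2 members were called smaller, Fkbp5 and Cebpd, and 1 larger, Suox, and adjusted over the list alone 11 were smaller and 1 larger. The call for Fkbp5 ended without each of 6 of the 8 libraries (adjusted p = 0.0766 to 0.177), all but replicate 1 of IPTG empty vector and replicate 2 of no IPTG in ethanol. That for Cebpd ended without each of 5 (adjusted p = 0.054 to 0.322), the same libraries except replicate 2 of no IPTG in dexamethasone. Each of the 5 states with IPTG had a smaller response of this list than no IPTG, with medians from -0.34 to -0.24 (fry adjusted p = 0.00237 to 0.00679). All 5 were compared with the same 4 libraries without IPTG, so they are not independent of each other. The response in wild-type NIPBL cells differed from that in IPTG empty vector by a median of 0.04 and did not pass (fry adjusted p = 0.811), nor did those of the mutants (medians -0.10 to 0.00; fry adjusted p = 0.498 to 0.993).

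**Figure D5:**
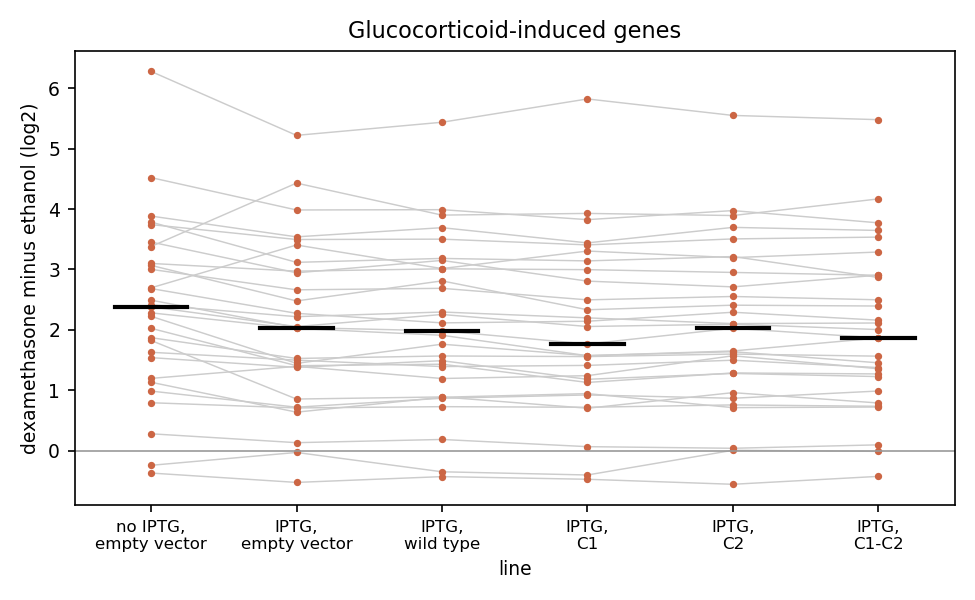
Log2 response to dexamethasone of the 29 measured glucocorticoid-induced genes (points, joined by gene) in each of the 6 cell states, with the median as a bar. The medians run from 2.38 without IPTG to between 1.77 and 2.04 in the states with IPTG.

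Between each mutant and wild-type NIPBL the responses differed in few genes. With C1 2 genes passed, Socs2 (difference -0.82) and Nrip1 (-0.44), and with C2 1 gene, Rps21, a ribosomal protein gene (0.61). With C1-C2 0 genes passed with edgeR, and DESeq2 called 0. For C1, C2 and C1-C2 734, 744 and 541 genes had an unadjusted edgeR p under 0.05, each below the 847 that chance would give. Nrip1 lost its call without any 1 of the 8 libraries of its comparison (adjusted p = 0.0546 to 0.414) and Socs2 without any but replicate 1 of wild-type NIPBL in dexamethasone (adjusted p = 0.0546 to 0.414). Rps21 lost it without replicate 1 of wild-type NIPBL in ethanol (adjusted p = 0.258) or in dexamethasone (0.0798), and without replicate 2 of C2 in ethanol (0.127) or in dexamethasone (0.177). For C1 the count was 0 without any 1 of the 4 ethanol libraries, without replicate 1 of C1 or without replicate 2 of wild-type NIPBL in dexamethasone, and 1 without replicate 2 of C1 in dexamethasone. For C2 the count was 0 without replicate 1 of wild-type NIPBL or replicate 2 of C2 in ethanol and without replicate 2 of C2 in dexamethasone, 3 without replicate 1 of C2 in ethanol or in dexamethasone, and 4 without replicate 2 of wild-type NIPBL in dexamethasone.

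Markers of blood and endothelial cells, looked at as a sign of other cells, held 3 measured genes, and none passed over all genes after knockdown or dexamethasone without IPTG with edgeR. Adjusted over the list alone 2 were higher after knockdown in dexamethasone, Cd68, a macrophage marker (1.19-fold, 10.8 ± 0.928 against 9.05 ± 0.319 CPM, SD, n = 2), and Cdh5, an endothelial cadherin with 4 counts against 0. Lyz2, a lysozyme gene of macrophages, was lower than in wild-type NIPBL with C1 in both treatments and with C2 in ethanol (1.95-fold for C1 and 1.89-fold for C2 in ethanol; edgeR adjusted p = 0.0167 and 0.025). Both C1 calls ended without any 1 of their 4 libraries (adjusted p = 0.072 to 0.16 in ethanol and 0.0501 to 0.167 in dexamethasone). The C2 call ended without replicate 1 or 2 of wild-type NIPBL (0.0987 and 0.161) or replicate 2 of C2 (0.375). Of 5 measured mammary epithelial genes 1 fell after knockdown in each treatment, Krt14, a basal keratin gene. Krt14 fell 1.34-fold in dexamethasone (edgeR adjusted p = 0.00207) and 1.29-fold in ethanol (edgeR adjusted p = 0.0117). The ethanol call ended without replicate 1 or 2 of IPTG empty vector (adjusted p = 0.0543 and 0.0939) and without replicate 2 of no IPTG (0.112). Krt14 was 1.41-fold higher with wild-type NIPBL in dexamethasone.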

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

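The differences of responses were planned before the data were examined. The tests of explanations were not in that plan. Those of the trend, depth and overlapping genes were written down before their own results were seen, and those of the library batch, the ethanol level, wild-type NIPBL and a single library were chosen only after the result was seen.

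A tested difference between responses to dexamethasone passed for 29 genes between knockdown and no IPTG. The 8 of smallest adjusted p were Tsc22d1 (-0.767 on the log2 scale), Socs2 (-1.164), Snx18 (-0.44), Lfng (-0.799), Notch1 (-0.781), Sphk1 (-0.709), Suox (0.709) and Rhob (-0.918), all from the edgeR fit. Of the lists, camera called a different response for glucocorticoid-induced genes (median -0.327; adjusted p = 0.0257 with an estimated correlation). It called p53 targets (median -0.119; adjusted p = 0.363 with an estimated correlation), immediate early genes (-0.234; 0.363), mitochondrially encoded genes (0.316; 0.596) and replication-dependent histone genes (-0.099; 0.498), and these calls were lost.

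For the C1 mutant against wild-type NIPBL a tested difference passed for 2 genes, Socs2 (-0.824) and Nrip1 (-0.439). Camera called glucocorticoid-induced genes (median -0.094), matrix and mesenchymal genes (0.075), cholesterol synthesis genes (0.103) and ribosomal protein genes (0.07), each lost (adjusted p = 0.853 with an estimated correlation). For C2 it passed for 1 gene, Rps21 (0.613). The lists called were cohesin genes (-0.083; adjusted p = 0.246 with an estimated correlation), mitochondrially encoded genes (0.315; 0.256), histone genes (0.195; 0.135) and ribosomal protein genes (0.144; 0.162), all lost. For C1-C2 the lists were cohesin genes (-0.061), histone genes (0.11) and ribosomal protein genes (0.083), all lost (adjusted p = 0.371 with an estimated correlation).

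The many calls in each dexamethasone response were weighed first. A trend with length or GC content may account for many of the calls without IPTG, of which 46.8% were kept after its removal, under the limit of 50% set beforehand, while in the other states 49.2% (C2) to 61.1% (wild-type NIPBL) were kept, above that limit in 4 of 5. Greater depth was excluded, since 94.1% were kept with each dexamethasone library thinned to the median total of the ethanol libraries. The glucocorticoid lists were called in the direction of the hormone far more often than other tested genes (larger 1-sided Fisher p of both lists 2.78e-05). This argues against a batch that acts alike on all genes as the whole cause for these lists. The test cannot exclude a part of a batch in their calls, as the library blocks match the treatments. For 3055 genes outside all 20 lists that were called in 1 direction in all 6 states a batch and the hormone cannot be told apart, because the library blocks match the treatments, and the same holds for members of the other lists.

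The smaller dexamethasone response of glucocorticoid-induced genes after knockdown was weighed next. It stayed after removal of the trend (median -0.297) and without any 1 library (highest median -0.274), so both were excluded. A raised level in ethanol was excluded, since the list was lower after knockdown in dexamethasone (median -0.337). Loss of NIPBL could be the cause, but a restored response with wild-type NIPBL did not pass (median 0.04, fry adjusted p = 0.811). Of the 29 members 21 lay above empty vector with wild-type NIPBL, and 10, 14 and 10 with C1, C2 and C1-C2. Against no IPTG the response differed in 0 genes with wild-type NIPBL and in 29, 37, 22 and 31 with empty vector, C1, C2 and C1-C2. Wild-type NIPBL nevertheless had the most genes at an unadjusted edgeR p under 0.05, 1289 against 857, 908, 791 and 793. The 0 therefore does not show that its response lay nearest to that without IPTG. The list itself still differed with wild-type NIPBL (median -0.241, fry adjusted p = 0.00679). From these values NIPBL loss and an effect of IPTG or the hairpin cannot be told apart. Incomplete add-back remains possible.

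Lower protocadherins after knockdown were weighed last. Reads shared between overlapping genes were excluded as the whole cause, since the 9 members without such an overlap were lower too (medians -1.041 and -1.331), but the fall was larger in the 19 with one (-3.048 and -3.174), so the size of the list median is uncertain. The trend was excluded (-2.177 after its removal), as was a single library (highest median -1.974 without 1). The list was higher with wild-type NIPBL than with empty vector (smaller median of both treatments 2.177). The medians were 1.733 and 2.095 in the 9 members without an overlap and 2.695 and 2.918 in the 19 with one. A rise with wild-type NIPBL fits a loss of NIPBL. In ethanol the list median against empty vector was 2.177 with wild-type NIPBL and 2.427 without IPTG. In dexamethasone it was 2.82 and 2.19, so wild-type NIPBL exceeded the level without IPTG. The 9 members without an overlap also rose more than they fell in both treatments. As the labels name 1 line per construct, a difference between lines could add to these values and was not tested. The knockdown itself compares empty-vector cells with and without IPTG.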

How the results depend on the processing

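The number of calls changed more when single libraries were left out than with the tool or the scaling, and the cause was not tested. Leaving out 1 of 2 libraries leaves 1 in the group, which is expected to lower the count whichever library it is. A fall alone therefore cannot be put down to the library left out. RLE factors, a strict filter and a fit without the 2 most abundant genes left all 20 counts within the same range, and with every scaling the median log2 change over all genes of a comparison was at most 0.0225 in size. Of the 152 calls of gene lists with the preset correlation, 26 held with an estimated correlation. DESeq2 gave 368 genes for C1-C2 in dexamethasone and 62, 5 and 6 for the differences of responses of the knockdown, C1 and C2. Without a low-count filter the counts in ethanol were 349 for wild-type NIPBL, 515 for C1, 569 for C2 and 289 for C1-C2, in dexamethasone 1211, 1399, 1540 and 517, and for the differences 85 (knockdown), 22 (C1), 33 (C2) and 10 (C1-C2). With a replicate block they were 392, 585, 683 and 299 in ethanol, 1395, 1621, 1750 and 550 in dexamethasone, and 71 (knockdown), 8 (C2) and 1 (C1-C2) for the differences, and recovery in ethanol was 0.032 for C1 (fry adjusted p = 0.0203) and 0.0282 for C1-C2 (0.0358). With a block within treatment they were 375, 575, 642 and 278, then 1377, 1573, 1698 and 540, and 77, 7, 9 and 2 for the differences. The labels do not say that replicate numbers pair across groups. Replicate differences correlated weakly (median 0.0527 over 66 pairs of groups, -0.221 to 0.283, 16 over 0.1), so some shared structure is possible, and the blocks were kept as alternatives. With only the libraries compared C2 and C1-C2 gave 169 and 211 in ethanol. Wild-type NIPBL, C1, C2 and C1-C2 gave 186, 280, 80 and 95 in dexamethasone. The differences gave 47 (knockdown), 0 (C1), 0 (C2) and 1 (C1-C2). For the mutants 525, 501 and 584 genes had an unadjusted p under 0.05, each below the 847 that chance would give over all 16934 tested genes.

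With the length and GC trend removed the dexamethasone responses gave 3858 without IPTG, 3531 in empty vector, 3620 in C1, 3385 in C2 and 3585 in C1-C2, and recovery of C1 in ethanol passed at 0.0316 (fry adjusted p = 0.0382). Small changes turned sign: Bag3 without IPTG to -0.051 (edgeR adjusted p = 0.549), and the Nipbl response to 0.018 in empty vector, 0.021 in wild-type NIPBL and 0.028 in C2, with 0.007 for the C2 difference. In the recovery set of at least 1.5-fold, C2 in ethanol gave 0.0588 (fry adjusted p = 0.173) and C1, C2 and C1-C2 in dexamethasone 0.0726 (0.0643), 0.0922 (0.0681) and 0.0692 (0.117). Without the library whose labels disagree C1-C2 in ethanol gave 38. Put in dexamethasone it gave 1 for the C1-C2 response, 17 for C1-C2 in ethanol and 140 in dexamethasone, and turned Cxcl1 (0.447), Ptgs2 (0.647) and Plk2 (0.326) of C1-C2 against wild-type NIPBL.

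With each library left out in turn, the counts ran from 1136 to 1551 for the knockdown in ethanol and 1374 to 2177 in dexamethasone. The dexamethasone responses ran from 4968 to 5396 without IPTG, 4000 to 4362 in empty vector, 3435 to 4459 in wild-type NIPBL, 3742 to 4627 in C1, 4197 to 4402 in C2 and 3715 to 4339 in C1-C2. In ethanol wild-type NIPBL ran from 66 to 93, C1 77 to 227, C2 62 to 418 and C1-C2 32 to 59, and in dexamethasone 165 to 1441, 216 to 1335, 128 to 1515 and 43 to 148. The differences ran from 9 to 24 (knockdown), 0 to 2 (C1), 0 to 4 (C2) and 0 to 0 (C1-C2). Recovery in ethanol ran from 0.2574 to 0.3389 for no IPTG, 0.0852 to 0.1312 for wild-type NIPBL, 0.0263 to 0.0364 for C1, 0.0438 to 0.065 for C2 and 0.0202 to 0.0365 for C1-C2, and in dexamethasone from 0.2854 to 0.3762, 0.1206 to 0.1694, 0.0303 to 0.0632, 0.0458 to 0.0762 and 0.0318 to 0.0615. The mutants minus wild-type NIPBL ran in ethanol from -0.0964 to -0.0464 (C1), -0.0839 to -0.0345 (C2) and -0.1072 to -0.0567 (C1-C2), and in dexamethasone from -0.1301 to -0.075, -0.1174 to -0.0602 and -0.1233 to -0.073.

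Some small values turned sign when 1 library was left out. Nipbl ran from -0.027 to 0.141 for wild-type NIPBL against empty vector in ethanol and -0.01 to 0.254 in dexamethasone, from -0.243 to 0.14 for C1 in ethanol, from -0.146 to 0.022 and -0.234 to 0.027 for C1-C2 in ethanol and dexamethasone, and for the differences from -0.295 to 0.088 (C1), -0.207 to 0.06 (C2) and -0.175 to 0.092 (C1-C2). Of the lists, cell cycle genes of C1 in ethanol ran from -0.006 to 0.152, cholesterol synthesis genes from -0.028 to 0.176 for the C1 difference and -0.238 to 0.038 for C2 in dexamethasone, and for C1-C2 in dexamethasone mitochondrially encoded genes from -0.591 to 0.071 and ribosomal protein genes from -0.035 to 0.096.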

Other observations

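The tests of neighbouring genes, gene span and distance were not part of the plan made before the data were examined. Each was written down after the knockdown calls were known and before its own result was seen, so none was chosen only after the result was seen.

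Among stress, cholesterol synthesis and clock genes dexamethasone raised some and lowered others. Herpud1, an endoplasmic reticulum stress gene, rose 2.76-fold without IPTG (edgeR adjusted p = 3.44e-15) while Ddit3, which encodes CHOP, fell 2.41-fold (edgeR adjusted p = 8.26e-09). The small heat shock gene Hspb1 rose 1.90-fold, and among cholesterol synthesis genes Fdps fell 2.07-fold and Insig1 1.88-fold. The clock gene Ciart rose 2.41-fold and Bhlhe40 fell 1.51-fold. Camera called none of the ATF4 and unfolded protein (6 of 18 higher, 3 lower), heat shock (3 of 11 higher, 1 lower) or cholesterol lists (3 of 18 higher, 6 lower).

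After knockdown the heat shock gene Hspb8 rose 1.21-fold in ethanol (edgeR adjusted p = 0.000349), and in dexamethasone Slc7a11 rose 2.65-fold, Trib3, a pseudokinase gene of the ATF4 response, 1.71-fold and Herpud1 fell 1.36-fold. Nr3c1 and the other 17 genes of the receptor, its chaperones and coregulators held no call in ethanol and 1 lower in dexamethasone. Cholesterol synthesis genes were called lower as a list in ethanol with 1 of 18 members higher and 0 lower over all genes and none over the list alone (median -0.12; adjusted p = 0.678 with an estimated correlation), and that call also ended without replicate 1 of no IPTG (camera adjusted p = 0.067) or replicate 2 of IPTG empty vector (0.0613). None of 15 mitochondrially encoded genes passed in either treatment. Ribosomal protein genes were lower in 3 of 30 in ethanol and 9 of 30 in dexamethasone (0 and 9 adjusted over the list alone; adjusted p = 0.381 and 0.259 with an estimated correlation).

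As a hypothesis, neighbouring genes may change in 1 direction when cohesin loading falls, as they might if they share a loop domain. Neighbouring genes that both changed after knockdown did so in 1 direction in 67.8% of 295 pairs in ethanol and 63.5% of 446 pairs in dexamethasone, where permuted directions gave a median of 50.2% and 50% (permutation p = 1e-04, 1-sided, the smallest that 10000 permutations can give). The lower value with the trend removed was 60.5% and without like gene names 60.6%, so a shared GC content and tandem families were excluded as the whole cause. Shared promoters or read-through remain possible and were not tested. Pairs that both rose and pairs that both fell were pooled, and no map of loop domains was used. The values therefore do not tell whether genes of a loop domain change, or lose expression, together. Whether neighbours share a direction as often in other comparisons was not tested.

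A further hypothesis was that lowered genes have longer bodies, as might follow if loop extrusion serves distant enhancers. The 745 lowered genes in both treatments, protocadherins left out, had a median span of 32.9 kb and the 801 raised in both 21.5 kb. All tested genes had a median of 14.3 kb, so raised genes were longer than these too. Lowered and raised genes had a difference of 11.4 kb (permutation p = 1e-04, 2-sided, the smallest that 10000 permutations can give), and with the trend removed the difference was 5.18 kb (permutation p = 0.009). The last hypothesis, that lowered genes may lie farther from other genes, was not borne out. The difference of medians was -0.144 kb (permutation p = 0.9, 2-sided), and -0.703 kb with the trend removed (permutation p = 0.2, 2-sided), and neither direction passed.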
